A study of Homo sapiens with 8 samples.

How the data were processed

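Messenger RNA was sequenced from CD1c+ dendritic cells isolated from the blood of 2 healthy donors, per the labels. The cells were kept for 6 h with medium only, with uninfected red blood cells (RBC), with RBC infected by Plasmodium falciparum at the schizont stage, or with lipopolysaccharide (LPS). The 4 groups held 2 libraries each, numbered replicate 1 and 2, so the series held 8 libraries. RNA was extracted with RNeasy Plus Micro columns and poly(A) libraries were made with a TruSeq stranded kit, per the labels' protocols. The deposited values were raw read counts per Ensembl gene, 1 file per library, with no normalization. TopHat2 2.1.0, HTSeq and the human genome build GRCh37 were named in the submitters' processing notes, without their roles or order. The counting mode, its strand setting, the annotation release and any read filter were not given in the sources used here. Genes with near-identical copies (HBA1 and HBA2, HSPA1A and HSPA1B, the MT1 family, HLA genes) and genes with an antisense partner therefore had uncertain counts.

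Each file held 57905 genes and 5 summary lines, of which 3 were at 0 in every library. Reads assigned to genes numbered from 13468990 to 23148200 per library. Reads assigned to no gene made up 4.81 to 8.88% and ambiguous reads 2.25 to 3.17% of the reads counted. A symbol was found for 52338 gene IDs in a table of gene names, and 5567 had none. Because the samples came from people, 474 genes linked to sex (Y-linked genes and the XIST region) were removed before testing. No coordinates were used.

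Counts were analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by trimmed mean of M-values (TMM), and low counts were removed with filterByExpr at its default settings, which left 13892 genes. A quasi-likelihood F-test with robust estimation was fitted to all 8 libraries as 4 groups, with no covariate. Contrasts were uninfected RBC against medium, infected RBC against uninfected RBC, LPS against medium, infected RBC against medium, infected RBC against LPS, and the difference between the effect of infected RBC over uninfected RBC and that of LPS over medium. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Every adjusted p of a gene comes from this test unless another is named. Levels are CPM, read counts normalised by edgeR to the TMM-scaled library sizes, given as mean ± SD of 2 libraries. The standard error (SE) of a log2 fold change was its size divided by the square root of F. With n = 2 the p-values measure only the spread between these samples, from 2 donors.

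A fold against a group with 0 reads was computed against a floor of 3 counts per library and is a lower bound. For a group with 1 to 3 reads a ratio of counts is given with its exact 95% interval. Floors and intervals cover counting error only, since reads carried no molecular identifiers. The biological coefficient of variation was 0.279. Within groups, log2 CPM correlated across genes at 0.963 to 0.977 between replicates, and genes are not independent replicates. The chi-square of counts per degree of freedom was 53.8 to 94.5, so the libraries were not copies or splits of 1 library, and 0 pairs were identical. The test was also run on simulated data made from the mean of each gene over all 8 libraries. In the LPS libraries 200 genes were changed, and LPS was compared with medium over 13294 genes tested. It recovered 10.1% of 109 genes changed 2-fold and 72.5% of 91 genes changed 4-fold. Of 82 genes called, 5 (6.1%) were unchanged.

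Fixed before the data were examined were the contrasts, the tests, all alternatives but 1, 31 gene lists and the rule for naming genes. The lists covered proinflammatory and T-cell-directing cytokines, chemokines, type I and III interferon genes, type I interferon-stimulated genes, interferon-gamma-inducible genes, costimulation and maturation, MHC class II presentation, MHC class I presentation, NF-kappaB targets and feedback, pattern-recognition receptors and adaptors, inflammasome and pyroptosis, and regulatory and inhibitory molecules. Further lists covered haem, iron and oxidative response, cholesterol synthesis and uptake, LXR targets and lipid efflux, glycolysis, stress and heat shock, metallothioneins and zinc transport, cell death regulators, and phagosome and lysosome. Cell type lists covered CD1c+ dendritic cell identity, CD141+ dendritic cells, plasmacytoid dendritic cells, monocytes, B cells, T cells, NK cells, neutrophils, platelets and erythroid cells, and a list of mitochondrially encoded genes tracked RNA quality. Of the list entries, 659 matched a gene ID and 6 did not (CCL3, CCL4, CCL5, CCL18, CCL23 and MRC1). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with a correlation estimated from the data, and their calls were also adjusted over the list alone.

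In each contrast the rule named the called genes with the highest and lowest log2 fold changes that reached 5 CPM in the higher group and moved the same way within both replicate numbers. From each list it named up to 4 called members with the smallest adjusted p or, where none was called, up to 2 with the highest CPM. Genes without a symbol, clone-named genes, pseudogenes, small RNAs, antigen receptor segments and genes whose presence depends on genotype were left out of the first part. Where 5 or fewer members of a list moved in a direction, those outside the rule were named after their values were seen. Some chosen genes are not reported here.

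The labels numbered the replicates alike in all 4 groups. Deviations from the group means of same-numbered libraries correlated across genes at 0.308 to 0.731 in all 6 pairs of groups. With 2 donors in the design text, the shared number was taken to mark the donor, and replicate number was fitted as a block in an alternative. Other alternatives were median-of-ratios size factors (RLE), no filter, the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the groups compared, removal of haemoglobin genes, and leaving out each library in turn. A library left alone in its group was then assumed to vary like the other groups. Library totals without scaling factors were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Groups of 2 were too small for a test of outlying samples or of other splits of the samples.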

Results

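Gene expression was measured by poly(A) RNA sequencing in CD1c+ dendritic cells, the most abundant conventional dendritic cells of blood, after 6 h in 4 conditions. The cells of 2 donors received medium only, uninfected red blood cells (RBC), RBC carrying schizonts of the malaria parasite Plasmodium falciparum, or lipopolysaccharide (LPS), the bacterial endotoxin sensed by TLR4. Each condition held 2 libraries, so n = 2 for every mean and SD. Reads assigned to genes in replicates 1 and 2 numbered 13468990 and 20923679 for medium, 21760199 and 21356571 for uninfected RBC, 20490408 and 16753554 for infected RBC, and 20646538 and 23148200 for LPS. The first principal component held 72.7% of the variance. Along it the medium and uninfected RBC libraries lay between -92.3 and -66.5, infected RBC at 25.1 and 55.7, and LPS at 116.8 and 121.8.

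Uninfected RBC were compared with medium to show what contact with red cells alone does. The clearest difference was in haemoglobin transcripts. HBB (ENSG00000244734), the beta chain, stood at 84.2 ± 49.96 CPM with uninfected RBC and had 0 reads in medium, which made it at least 554-fold higher. HBA2 and HBA1, near-identical alpha chain genes whose reads cannot be assigned with certainty, stood at 26.0 ± 8.19 and 6.84 ± 2.24 CPM, at least 171-fold and 45.0-fold higher than their 0 reads in medium. The group means of inflammatory genes differed by less than the SD between libraries: IL1B was at 294 ± 22.0 CPM against 297 ± 159 in medium, and CXCL8 at 592 ± 116 against 624 ± 317. That SD does not measure the change within a replicate number. CD1c+ dendritic cell genes were also close, with FCER1A at 1073 ± 311 CPM against 987 ± 360.

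No gene passed the threshold in this comparison. The adjusted p was 0.0827 for HBB (1.8e-90 to 1 over the alternatives), 0.236 for HBA2 and 0.83 for HBA1. The quasi-likelihood test of edgeR called 0 of 13892 genes with 19 at an unadjusted p below 0.05, DESeq2 called 2 (HBB and HBA2) and limma-voom 0. HBB was the 1 gene called with replicate number as a block (adjusted p = 0.015) and the 1 called without replicate 2 of uninfected RBC (adjusted p = 0.0135). Among the 11 measured erythroid genes 3 rose adjusted over the list alone, and the list was called higher (camera adjusted p = 1.12e-14), though not at an adjusted p = 0.0588 with an estimated correlation. Its median log2 fold change was 0.16 against a mean of 3.34, and it was not called with haemoglobin genes removed. The 15 mitochondrially encoded genes were lower as a list (adjusted p = 0.0173) with 0 called members, and had an adjusted p = 0.991 with an estimated correlation. Those were the 2 lists called. The number of lists called was 10 without replicate 1 of medium, 12 without replicate 2 of medium, 12 without replicate 1 of uninfected RBC and 8 without replicate 2 of uninfected RBC.

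Infected and uninfected RBC were then compared, with contact with red cells common to both. The 2 kinds of library also differed in haemoglobin reads, so the comparison may hold more than infection itself. Inflammatory transcripts were far higher with infected RBC, while genes typical of resting dendritic cells were lower. IL6 (ENSG00000136244), an acute-phase cytokine, went from 0.592 ± 0.276 CPM with uninfected RBC to 125 ± 136 CPM with infected RBC (208-fold, log2 fold change 7.70, SE 1.13, adjusted p = 0.00629). The 2 infected libraries stood apart from each other for this gene, at 28.9 CPM in replicate 1 and 221 in replicate 2. IL12B, the chain shared by IL-12 and IL-23, went from 0.234 ± 0.119 to 55.5 ± 46.0 CPM (233-fold). DLL4, a Notch ligand, and IL36G, an IL-1 family cytokine, had 0 reads with uninfected RBC and were at least 174-fold and 55.4-fold higher with infected RBC. SLAMF1, a leukocyte receptor, rose 667-fold, the transcription factor BATF 559-fold, and TNIP3, an inhibitor of NF-kappaB signalling, 230-fold.

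Among the genes that fell, FCER1A (ENSG00000179639), the alpha chain of the IgE receptor and a marker of CD1c+ dendritic cells, went from 1073 ± 311 to 27.9 ± 9.99 CPM (38.5-fold lower, adjusted p = 0.00199). KIT, the receptor for stem cell factor, fell 43.2-fold, from 128 ± 8.98 to 3.01 ± 1.66 CPM. SLC46A2 and LINC03058 kept a few reads with infected RBC, with count ratios of 177 (95% interval 48.7 to 1460) and 125 (34.5 to 1040). Haemoglobin reads were nearly confined to the uninfected RBC libraries: HBA2 was at least 137-fold and HBA1 at least 36.1-fold lower with infected RBC, and HBB had a count ratio of 2690 (483 to 1.06e+05).

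In this comparison 2732 of 13892 genes were called, 1606 higher and 1126 lower with infected RBC. With replicate number as a block the count was 4302, and with the 4 libraries of the 2 groups alone 1677. It fell to 420 without replicate 2 of uninfected RBC, 1235 without replicate 1 of uninfected RBC and 1367 without replicate 2 of infected RBC. Of the 144 called genes chosen for naming in this comparison, 57, 100 and 110 were called without those libraries, and none reversed. Scaling set the balance of directions: 58.8% of calls were higher with TMM and 24.7% with library totals alone, which shifted the median of all genes by -0.47 on the log2 scale.

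Cytokine and chemokine genes rose together. Of 25 measured proinflammatory and T-cell-directing cytokines, 18 rose and 1 fell, TNFSF13B, a B-cell survival factor (20 and 1 adjusted over the list alone, camera adjusted p = 1.27e-08). CSF2, the growth factor GM-CSF, rose 51.8-fold to 6.34 ± 0.939 CPM, and OSM, an IL-6 family cytokine, rose 3.07-fold. Of 20 measured chemokines, 13 rose and CXCL16, a membrane-bound chemokine, fell (18 and 1 adjusted over the list alone, adjusted p = 1.22e-08). CXCL2 rose 6.36-fold to 125 ± 9.10 CPM, CCL2, which draws monocytes, 47.3-fold to 243 ± 1.05 CPM, and CXCL8, which draws neutrophils, 8.55-fold to 5065 ± 359 CPM. With RLE size factors CXCL16 was no longer called (adjusted p = 0.0589). Both lists had an adjusted p = 0.265 with an estimated correlation.

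**Figure D1:**
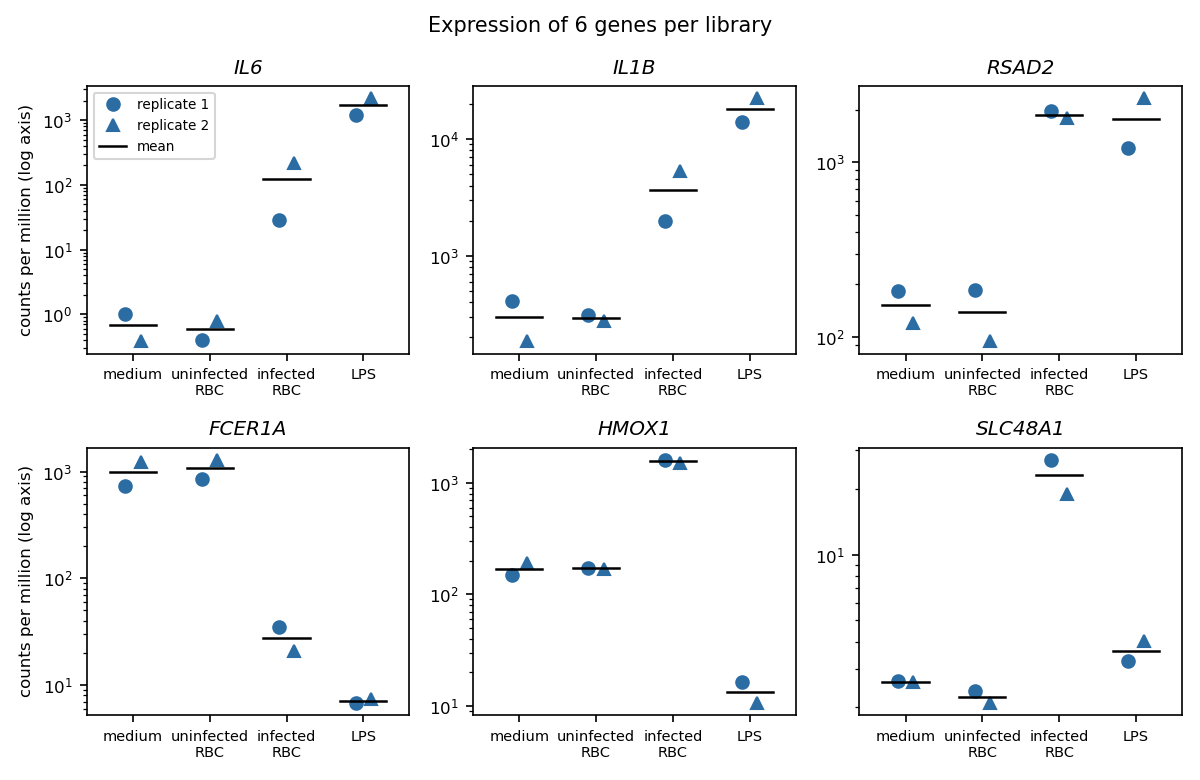
Expression of 6 genes in CPM on a log axis in each of the 8 libraries, by condition, with circles for replicate 1, triangles for replicate 2 and a line at the mean. IL6, IL1B and RSAD2 were higher and FCER1A lower with infected RBC and with LPS than in their controls, while HMOX1 was at 1565 CPM with infected RBC and 13.4 CPM with LPS.

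Interferon-stimulated genes rose almost without exception. Of 46 measured type I interferon-stimulated genes, 42 rose and 0 fell by the edgeR test (44 and 0 adjusted over the list alone, adjusted p = 8.52e-22). IFI27 rose 13.0-fold, and RSAD2, the antiviral protein viperin, rose 13.4-fold from 140 ± 63.9 to 1868 ± 122 CPM. Among 24 interferon-gamma-inducible genes 17 rose and 0 fell, or 16 and 1 with library totals (20 and 1 adjusted over the list alone, adjusted p = 3.47e-09). PSTPIP2 rose 4.81-fold and IL15RA, which presents IL-15, 46.7-fold. Each list had an adjusted p = 0.265 with an estimated correlation. Of the type I and III interferon genes only IFNB1 had enough reads to test, at 0.173 ± 0.0202 CPM with uninfected and 0.226 ± 0.0896 with infected RBC (log2 fold change 0.33, SE 1.07, adjusted p = 0.858), and its direction turned with library totals (-0.13) and without replicate 2 of infected RBC (-0.10).

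Costimulation and class I presentation genes mostly rose, while 5 class II presentation genes fell. Of 28 measured costimulation and maturation genes, 16 rose and TNFSF4, the OX40 ligand, fell (21 and 1 adjusted over the list alone, adjusted p = 7.32e-09, adjusted p = 0.314 with an estimated correlation). SLAMF7 rose 15.6-fold, CD274, the inhibitory ligand PD-L1, 23.6-fold to 596 ± 395 CPM, and IL2RA 161-fold. Of 21 MHC class I presentation genes 13 rose and 0 fell, or 7 and 1 with library totals (18 and 0 adjusted over the list alone, adjusted p = 1.3e-08, adjusted p = 0.265 with an estimated correlation). CALR, a chaperone of class I molecules, rose 2.80-fold to 1711 ± 13.4 CPM, NLRC5, their transactivator, 8.88-fold and TAP1, a peptide transporter, 3.29-fold. Of 20 MHC class II presentation genes 0 rose and 5 fell: MARCHF1, an enzyme that marks class II molecules for removal (5.76-fold lower), CD1C (2.54-fold), CD1E, HLA-DOA and HLA-DMB (1 and 5 adjusted over the list alone, adjusted p = 0.238). Class II genes gave 1 higher and 5 lower with replicate number as a block and 0 and 8 with library totals. Reads of HLA genes are uncertain because paralogs resemble each other.

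NF-kappaB targets and regulatory molecules were called as lists, and receptor and inflammasome genes were not. Of 30 measured NF-kappaB targets and feedback genes 26 rose and 0 fell (28 and 0 adjusted over the list alone, adjusted p = 1.34e-15, adjusted p = 0.265 with an estimated correlation). PLAUR, the urokinase receptor, rose 4.67-fold, SOD2, a mitochondrial superoxide dismutase, 7.99-fold to 9847 ± 3355 CPM, and IRAK3, a brake on TLR signalling, 3.13-fold. Among 28 pattern-recognition receptors and adaptors 7 rose and 4 fell (9 and 4 adjusted over the list alone, adjusted p = 0.977), and the sign of the list's median turned with library totals. The counts were 9 and 7 with replicate number as a block and 5 and 8 with library totals. Those that fell were TLR6, TLR1, TIRAP and CD14, while NOD1 rose 3.83-fold and TLR2 3.38-fold. Of 18 inflammasome and pyroptosis genes 5 rose, P2RX7, IL1RN, IL1B, IL1A and AIM2, and NLRC4 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0685), while the block gave 8 higher and 2 lower and library totals 4 and 5. IL1B rose 12.4-fold to 3647 ± 2334 CPM and IL1RN, the natural antagonist of IL-1, 40.3-fold. Of 25 regulatory and inhibitory molecules 12 rose, CISH 14.0-fold and LILRB4 4.46-fold among them, and TSC22D3 and CD200R1 fell (16 and 2 adjusted over the list alone, adjusted p = 9.57e-06, adjusted p = 0.265 with an estimated correlation).

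Haem and iron genes rose together with infected RBC. HMOX1 (ENSG00000100292), the haem oxygenase that breaks haem down, went from 172 ± 2.24 to 1565 ± 65.5 CPM (9.12-fold, log2 fold change 3.19, SE 0.26, adjusted p = 0.00199). SLC48A1, a transporter that moves haem out of lysosomes, rose 10.3-fold to 23.0 ± 5.90 CPM. TXN, thioredoxin, rose 8.44-fold and FTL, the ferritin light chain that stores iron, 3.16-fold. Of 26 measured genes of the haem, iron and oxidative response 16 rose and LRP1 fell (21 and 3 adjusted over the list alone, adjusted p = 7.1e-08). The counts were 17 and 3 with replicate number as a block and 15 and 3 with library totals. Of 10 metallothioneins and zinc transporters 7 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 8.73e-05). MT2A, a metal-binding protein, rose 46.1-fold, though members of this family share reads. Of 25 stress and heat shock genes 13 rose and CHAC1 fell (13 and 1 adjusted over the list alone, adjusted p = 2.92e-06), with the chaperone HSPA5 at 5.26-fold. These 3 lists had an adjusted p = 0.265 with an estimated correlation.

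Of the metabolic, vesicle and cell death lists, all but the LXR targets were called. Of 21 cholesterol synthesis and uptake genes 7 rose, INSIG1 2.72-fold among them, and 0 fell, or 15 and 0 with replicate number as a block (10 and 0 adjusted over the list alone, adjusted p = 4.28e-07). Of 21 glycolysis genes 6 rose, with the glucose transporter SLC2A3 at 5.98-fold, and PDK1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0104). Of 26 phagosome and lysosome genes 9 rose, led by the protease CTSL at 28.2-fold, and 3 fell, FCGR2B and HEXA among them (11 and 5 adjusted over the list alone, adjusted p = 0.00583). The block gave 13 higher and 4 lower for that list, and with library totals the balance turned, to 3 and 5. With an estimated correlation these 3 lists had an adjusted p = 0.265. Of 21 cell death regulators 6 rose, with the survival factor BCL2L1 at 9.12-fold, while CASP8 and TNFRSF10B (not called with RLE size factors) fell (8 and 3 adjusted over the list alone, adjusted p = 0.0399, adjusted p = 0.357 with an estimated correlation). Of 15 LXR targets and lipid efflux genes FASN, fatty acid synthase, rose 2.19-fold and LPCAT3 fell 1.91-fold (3 and 1 adjusted over the list alone, adjusted p = 0.38), and 6 rose and 1 fell with replicate number as a block.

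Marker genes of the dendritic cells themselves mostly fell. Of 16 CD1c+ dendritic cell identity genes 9 fell and 2 rose, ITGAX and IRF4 (9 and 2 adjusted over the list alone, adjusted p = 0.00583, adjusted p = 0.265 with an estimated correlation). CLEC10A, a lectin of these cells, fell 6.28-fold and CD2 4.90-fold. Of 15 monocyte genes 4 fell, FCGR3A 8.41-fold, MS4A6A 7.76-fold, VCAN and CD14, and 2 rose, S100A9 and S100A12 (6 and 5 adjusted over the list alone, adjusted p = 0.38). The monocyte counts were 7 lower and 5 higher with replicate number as a block and 7 and 1 with library totals. Of 11 erythroid genes HBB, HBA2, HBA1 and STRADB were among those that fell, and GYPC rose, with 7 lower and 0 higher with library totals (5 and 2 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.265 with an estimated correlation). Of 8 platelet genes ITGB3, GP1BA and GNG11 rose, with 2 higher and 1 lower with library totals (3 adjusted over the list alone, adjusted p = 0.117). Of 6 B-cell genes CD22, FCER2 and PAX5 rose (3 adjusted over the list alone, adjusted p = 0.253). Of 8 CD141+ dendritic cell genes BATF3 and ZNF366 rose (2 up and 2 down adjusted over the list alone, adjusted p = 0.741), and the block and library totals each gave 2 higher and 2 lower. NRP1 rose among 9 plasmacytoid dendritic cell genes (1 adjusted over the list alone, adjusted p = 0.653), where the block gave 1 higher and 1 lower and library totals 1 and 3. CD28 fell among 8 T-cell genes, or 2 with the block and with library totals (1 adjusted over the list alone, adjusted p = 0.238). MMP9 rose and CXCR2 fell among 4 neutrophil genes (adjusted p = 0.863). The edgeR test called 0 of 3 NK-cell genes (1 adjusted over the list alone, adjusted p = 0.72; with replicate number as a block NCAM1 was called, adjusted p = 0.0364) and 0 of 15 mitochondrially encoded genes (adjusted p = 0.407), and the medians of both lists changed sign with library totals.

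LPS was compared with medium as the reference stimulus. It was followed by the largest number of changed genes of the 6 contrasts. ZBTB32, a transcriptional repressor, and IL27, a cytokine subunit, had 0 reads in medium and reached 255 ± 124 and 58.2 ± 27.7 CPM, at least 1680-fold and 383-fold higher. CFB, complement factor B, was at least 280-fold higher. DLL4 and IL36G had 1 to 3 reads in medium, with count ratios of 6230 (95% interval 1120 to 2.46e+05) and 5680 (1020 to 2.25e+05). Some genes that fell had 0 reads with LPS, so that only a lower bound can be given: RNASE1, a secreted ribonuclease, was at least 114-fold lower, MPZL2 at least 110-fold and PEAK3 at least 36.9-fold. MYCL, a MYC family transcription factor with a role in dendritic cells, fell 345-fold from 102 ± 12.4 to 0.291 ± 0.0917 CPM, and KIT fell 270-fold.

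With LPS 5424 of 13892 genes were called, 2771 higher and 2653 lower. The count was 3044 without replicate 2 of medium and 3400 without replicate 2 of LPS. Of the 173 called genes chosen for naming in this comparison, 136 and 137 were called without those libraries. Higher calls made up 51.1% with TMM and 23.6% with library totals alone, which shifted the median of all genes by -0.62 on the log2 scale.

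The inflammatory lists rose with LPS as with infected RBC. Of 25 cytokines 19 rose, and IL18 and TNFSF13B fell, or 18 and 4 with library totals (20 and 3 adjusted over the list alone, camera adjusted p = 1.55e-06). IL23A, a subunit of IL-23, rose 159-fold to 584 ± 25.8 CPM. CSF2 had a count ratio of 685 (95% interval 234 to 3320). Of 20 chemokines 16 rose and CXCL16 fell (16 and 1 adjusted over the list alone, adjusted p = 2.94e-06). CXCL2 rose 37.2-fold to 740 ± 69.4 CPM and CXCL8 32.4-fold. Of 46 type I interferon-stimulated genes 43 rose and 0 fell by the edgeR test (45 and 0 adjusted over the list alone, adjusted p = 1.33e-18), with IFI27 at 151-fold and HERC6 at 15.1-fold. IFNB1 itself, the interferon-beta gene, rose 16.9-fold to 2.05 ± 2.06 CPM (adjusted p = 0.0135). Of 24 interferon-gamma-inducible genes 19 rose and CIITA, the class II transactivator, fell (21 and 1 adjusted over the list alone, adjusted p = 3.22e-08). Of 30 NF-kappaB targets 25 rose and 0 fell (27 and 0 adjusted over the list alone, adjusted p = 4.6e-12), with TNFAIP6 at 92.3-fold. With an estimated correlation these lists had an adjusted p = 0.367.

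With LPS class I presentation genes rose and class II genes mostly fell. Of 20 MHC class II presentation genes 11 fell, HLA-DOA 8.22-fold and HLA-DMB, which loads peptides, 10.8-fold from 605 ± 154 to 56.1 ± 15.2 CPM, and CTSS and HLA-DOB rose, or 16 and 0 with library totals (11 and 2 adjusted over the list alone, adjusted p = 0.000124). Of 21 MHC class I genes 19 rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p = 1.23e-09), with the peptide trimmer ERAP1 at 3.41-fold and TAP2 at 6.41-fold. Both had an adjusted p = 0.35 with an estimated correlation. Of 28 costimulation and maturation genes 18 rose, and TNFSF4 (75.5-fold) and ICOSLG fell, or 13 and 4 with library totals (19 and 2 adjusted over the list alone, adjusted p = 2.33e-05, adjusted p = 0.478 with an estimated correlation). Of 28 pattern-recognition receptors and adaptors 7 rose and 10 fell (8 and 10 adjusted over the list alone, adjusted p = 0.614), TLR6 6.29-fold lower and NOD1 9.43-fold higher. Of 18 inflammasome genes 7 rose, IL1B 61.2-fold and AIM2 16.6-fold among them, and PYCARD, NLRC4, IL18, NLRP1 and IL18BP fell (8 and 5 adjusted over the list alone, adjusted p = 0.409). Of 25 regulatory molecules 14 rose, IL10 155-fold to 248 ± 77.3 CPM among them, and TSC22D3, CD200R1, HAVCR2 and IL18BP fell (15 and 4 adjusted over the list alone, adjusted p = 0.00299, adjusted p = 0.367 with an estimated correlation). With library totals the median of the inflammasome list changed sign, with 7 higher and 9 lower, and with RLE size factors IL18BP was not called (adjusted p = 0.0502).

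In the haem and metabolic lists, HMOX1 fell with LPS from 170 ± 28.96 to 13.4 ± 3.93 CPM (12.6-fold lower, log2 fold change -3.66, SE 0.27, adjusted p = 0.000258). LRP1 and CD163 also fell and 13 of the 26 genes of this list rose, TXN 20.6-fold and MAFG 4.15-fold (13 and 4 adjusted over the list alone, adjusted p = 0.0263, adjusted p = 0.367 with an estimated correlation). Of 25 stress and heat shock genes 20 rose and 0 fell, or 12 and 0 with library totals (20 and 0 adjusted over the list alone, adjusted p = 9.62e-09, adjusted p = 0.35 with an estimated correlation), with XBP1, a factor of the unfolded protein response, at 4.88-fold. Of 10 metallothioneins 6 rose, MT2A 160-fold, and 0 fell, or 7 and 1 with replicate number as a block and 4 and 1 with library totals (8 and 1 adjusted over the list alone, adjusted p = 0.00741, adjusted p = 0.367 with an estimated correlation). Of 21 cholesterol genes 6 rose and 0 fell, or 12 and 2 with replicate number as a block and 3 and 3 with library totals (4 and 0 adjusted over the list alone, adjusted p = 0.0306, adjusted p = 0.586 with an estimated correlation), with a median that changed sign with library totals. Of 21 cell death regulators 9 rose, BCL2L1 27.2-fold, and CASP8, TP53I3 and BIK fell (9 and 4 adjusted over the list alone, adjusted p = 0.0466, or 0.0508 with replicate number as a block, adjusted p = 0.435 with an estimated correlation). The median of that list also changed sign with library totals, which gave 7 and 5, and RLE size factors gave 9 and 1, without TP53I3 and BIK. Of 15 LXR targets ABCA1, the cholesterol exporter, rose 13.9-fold with SMPDL3A, while LPCAT3, CD36, MYLIP and ABCG1 (not called with RLE size factors) fell, or 1 and 8 with library totals (2 and 4 adjusted over the list alone, adjusted p = 0.199). Of 21 glycolysis genes 7 rose and TPI1, GPI, PFKL and GAPDH (not called with RLE size factors) fell (7 and 4 adjusted over the list alone, adjusted p = 0.409), and the list's median changed sign with library totals, with 4 higher and 8 lower. Of 26 phagosome and lysosome genes 6 rose and 11 fell, TFEB, a regulator of lysosome genes, 4.33-fold (6 and 11 adjusted over the list alone, adjusted p = 0.364).

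Of 16 CD1c+ dendritic cell identity genes 12 fell with LPS and 0 rose by the edgeR test (12 and 0 adjusted over the list alone, adjusted p = 1.11e-05, adjusted p = 0.222 with an estimated correlation). CLEC10A fell 105-fold and FCER1A 138-fold, from 987 ± 360 to 7.15 ± 0.456 CPM. Of 15 monocyte genes 9 fell, FCGR3A 29.9-fold and CD14, a co-receptor for LPS, 11.3-fold, and S100A12, S100A9 and CES1 rose (9 and 4 adjusted over the list alone, adjusted p = 0.0466, adjusted p = 0.367 with an estimated correlation). Of 8 platelet genes PPBP, GP1BA, GP9, GNG11 and CLU rose (5 adjusted over the list alone, adjusted p = 0.0181, adjusted p = 0.35 with an estimated correlation), PPBP from 0.317 ± 0.0922 to 3.26 ± 1.17 CPM. Of 11 erythroid genes GYPC and SLC25A37 rose and EPB41, SLC25A39 and BNIP3L were among those that fell (2 and 4 adjusted over the list alone, adjusted p = 0.614). Among 9 plasmacytoid dendritic cell genes NRP1 and LAMP5 rose and SPIB, SERPINF1 and GZMB fell (adjusted p = 0.902). Among 8 CD141+ dendritic cell genes BATF3 and ZNF366 rose and WDFY4 and CPNE3 fell (adjusted p = 0.579). FCER2, PAX5 and CD22 rose among 6 B-cell genes (adjusted p = 0.199). CD5 and CD28 were among the called of 8 T-cell genes and fell (adjusted p = 0.25, with 0 higher and 4 lower with library totals), CD5 23.6-fold from 398 ± 106 CPM. NKG7 fell among 3 NK-cell genes (adjusted p = 0.667) and LTF rose among 4 neutrophil genes (adjusted p = 0.409). The edgeR test called 0 of 15 mitochondrially encoded genes (adjusted p = 0.902), and that list's median changed sign with library totals, with 1 called lower.

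**Figure D2:**
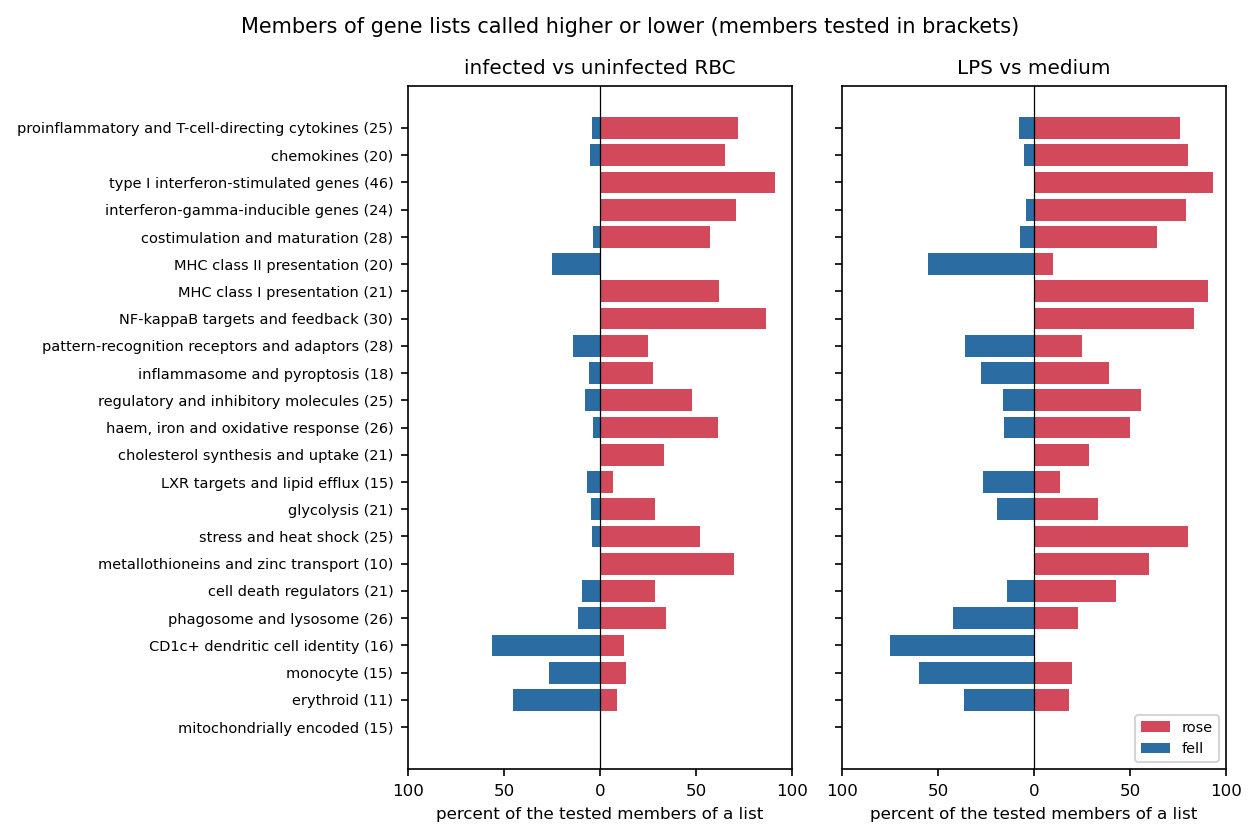
Percent of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left), for infected against uninfected RBC and for LPS against medium, in lists with at least 10 tested members. Type I interferon-stimulated genes rose in both comparisons (42 and 43 of 46), and CD1c+ dendritic cell identity genes fell in both (9 and 12 of 16).

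Most genes called with infected RBC were also called with LPS. Of the 2732 genes called with infected RBC over uninfected RBC, 2291 (83.9%) were called in the same direction with LPS over medium. Of the 5424 genes called with LPS, 3110 were not called with infected RBC. The count was 1344 higher in both, where independent lists would share 320.3, and 947 lower in both, where they would share 215. The 2 contrasts share no library, but they share both donors if replicate number marks the donor. Groups simulated without change shared at most 1 call. At most 2 genes were called per contrast there, so the simulations set no expectation for the overlap of long lists. Across the 13892 genes the log2 fold changes correlated at r = 0.807 and rho = 0.761, with a covariance of 2.18. The mean covariance was 0.0011 in the simulations, which drew each library independently and so held no shared donors. Genes are not independent replicates. Of the genes called in both in the same direction, 79% changed more with LPS, and the median ratio of the changes was 0.768. The 2291 shared calls were 3479 with replicate number as a block and 3799 with library totals alone. They were 395 without replicate 2 of uninfected RBC, 1133 without replicate 1 of uninfected RBC and 1188 without replicate 2 of infected RBC.

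Opposite calls were few, 18 genes higher with infected RBC and lower with LPS, where independent lists would share 306.7, and 5 the other way round, against 224.6. Among the 18 were HMOX1, the lysosomal protease CTSD (46.2 CPM with uninfected RBC, 158 with infected RBC, 49.9 in medium and 5.81 with LPS), the integrin genes ITGAX and ITGB2, the growth factor HBEGF, the sterol hydroxylase CYP27A1, the retinal dehydrogenase ALDH1A2 and the serine dehydratase SDS. Among the 5 others were PHF19, CHAC1, GRIP1 and PGBD5 (not called with infected RBC with RLE size factors, adjusted p = 0.0501). GRIP1 and PGBD5 had few reads, with group means of at most 2.39 and 1.44 CPM, so the size of their changes is uncertain. All the genes with opposite calls given here were named after their values were seen. The difference between the effects was called for 18 of the 23, which is no independent evidence, since the opposite calls that chose these genes come from the same libraries. Leaving out 1 library lowered the number of opposite calls, most of all without either library of uninfected RBC. The exception was replicate 2 of infected RBC, without which the number rose. Such fits borrow the spread of the remaining library from the other groups. The blocked fit gave 63 opposite calls and the fit with no filter 50.

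**Figure D3:**
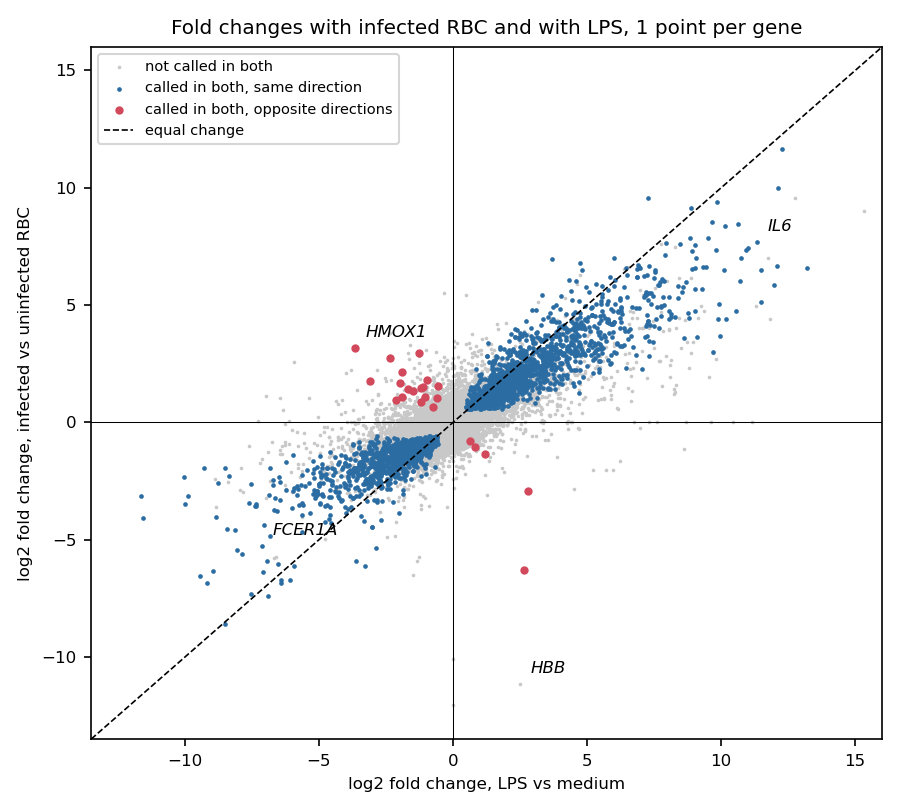
Log2 fold change of LPS over medium (horizontal) against that of infected over uninfected RBC (vertical), 1 point per gene, with blue for genes called in the same direction in both, red for genes called in opposite directions, grey for the rest, and a dashed line at equal change. Most of the 2291 blue points lie between the dashed line and no change with infected RBC, and HMOX1 lies in the quadrant of genes higher with infected RBC and lower with LPS.

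A direct contrast of infected RBC with LPS asked where the 2 stimuli differ, with any effect of red cells themselves included. HMOX1 was 117-fold higher with infected RBC than with LPS (log2 fold change 6.87, SE 0.31, adjusted p = 0.000503). SDS was 35.1-fold higher and TNFSF14, the cytokine LIGHT, 37.2-fold. Genes found almost only with LPS included SERPINB7, a protease inhibitor (107 ± 31.9 CPM with LPS, 0.126 ± 0.0257 with infected RBC, 825-fold lower), and the anion transporter SLC26A9, which had 0 reads with infected RBC (at least 125-fold lower). LCT, lactase, and its antisense gene LCT-AS1 were at least 74.2-fold and 46.0-fold lower, but their reads cannot be told apart without the strand setting. In all 1247 genes were called, 780 higher and 467 lower with infected RBC, and 2429 with replicate number as a block. The count was 233 without replicate 2 of LPS, 316 without replicate 1 of LPS, 689 without replicate 1 of infected RBC and 484 with only these 4 libraries. Library totals alone shifted the median of all genes by 0.13 on the log2 scale.

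Lists of dendritic cell, monocyte, class II, lysosome, LXR and cholesterol genes were higher with infected RBC than with LPS. Of 16 CD1c+ dendritic cell identity genes 10 were higher, CLEC10A 17.6-fold and ITGAX 2.85-fold among them, and 0 lower by the edgeR test (10 and 0 adjusted over the list alone, adjusted p = 2.17e-07, adjusted p = 0.103 with an estimated correlation). Of 20 MHC class II genes 9 were higher, HLA-DOA 4.90-fold and HLA-DMA 2.44-fold among them, and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 4.97e-07, adjusted p = 0.205 with an estimated correlation). Of 26 phagosome and lysosome genes 12 were higher, CTSD 27.2-fold and TFEB 3.17-fold among them, and 1 was lower (14 and 1 adjusted over the list alone, adjusted p = 9.53e-06, adjusted p = 0.283 with an estimated correlation). Of 15 monocyte genes 5 were higher, CD14 and FCGR3A among them, and 0 lower by the edgeR test (8 and 1 adjusted over the list alone, adjusted p = 0.00595, adjusted p = 0.283 with an estimated correlation). Of 21 cholesterol genes FDPS and MVD were higher (3 and 0 adjusted over the list alone, adjusted p = 0.0236, adjusted p = 0.632 with an estimated correlation). HMOX1, SLC48A1, FTL and LRP1 were among the genes of the haem list that were higher (7 and 2 adjusted over the list alone, adjusted p = 0.151), as were LPCAT3, FASN, SREBF1 and CD36 of the LXR list (9 and 0 adjusted over the list alone, adjusted p = 0.00187, adjusted p = 0.205 with an estimated correlation). The counts higher and lower with replicate number as a block were 14 and 0 for class II, 7 and 1 for monocyte, 7 and 1 for cholesterol, 7 and 3 for haem and 9 and 1 for LXR genes.

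Lists of cytokine, interferon-responsive, class I, NF-kappaB and stress genes were lower with infected RBC than with LPS, with few called members in most. Of 20 chemokines 6 were lower with infected RBC, CXCL2 5.91-fold, CXCL1 9.95-fold, CXCL3 2.85-fold and CXCL8 3.99-fold among them, and CXCL16 and CCL24 were higher (6 and 2 adjusted over the list alone, adjusted p = 0.0575). Of 25 cytokines 6 were lower, IL36G 21.3-fold and CSF2 7.66-fold among them, and OSM and IL18 were higher (11 and 2 adjusted over the list alone, adjusted p = 0.000428). IFI27 was 12.7-fold lower, and HERC6 and ZBP1 were the other called members of the 46 interferon-stimulated genes (8 adjusted over the list alone, adjusted p = 5.81e-07). Of 24 interferon-gamma-inducible genes CD38 and WARS1 were lower (2 adjusted over the list alone, adjusted p = 0.00651). The cytokine list and these 2 interferon lists had an adjusted p = 0.632 with an estimated correlation. ERAP1 and HLA-E were lower among 21 MHC class I genes (2 adjusted over the list alone, adjusted p = 8.47e-05, adjusted p = 0.568 with an estimated correlation), and TNFAIP6 among 30 NF-kappaB targets (1 adjusted over the list alone, adjusted p = 0.00964, adjusted p = 0.641 with an estimated correlation). CHAC1, HSPH1 and XBP1 were among 6 of 25 stress genes lower with infected RBC (10 adjusted over the list alone, adjusted p = 4.54e-05, adjusted p = 0.49 with an estimated correlation). The counts lower with replicate number as a block were 7 for interferon-stimulated, 4 for interferon-gamma-inducible (with 1 higher), 3 for NF-kappaB and 11 for stress genes. With library totals 7 interferon-stimulated genes and 0 class I genes were lower.

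Infected RBC were also set against medium, for the whole response to the infected cells. SLAMF1 rose 619-fold and IL2RA, the IL-2 receptor alpha chain, 263-fold, while KIT fell 37.4-fold and FCER1A 35.4-fold, from 987 ± 360 to 27.9 ± 9.99 CPM. In all 2521 genes were called, 1537 higher and 984 lower. Of 46 type I interferon-stimulated genes 42 rose and 0 fell by the edgeR test (adjusted p = 3.5e-21), and of 30 NF-kappaB targets 26 rose (adjusted p = 7.24e-16). Of 26 haem and iron genes 14 rose and 1 fell, or 17 and 2 with replicate number as a block (adjusted p = 2.91e-07), and of 16 CD1c+ dendritic cell identity genes 9 fell and 2 rose (adjusted p = 0.00738). With an estimated correlation these 4 lists had an adjusted p = 0.271. The count of genes was 4122 with replicate number as a block, 1433 with only these 4 libraries, 288 without replicate 2 of medium, 1521 without replicate 1 of medium and 1276 without replicate 2 of infected RBC. Higher calls made up 61.0% with TMM and 24.4% with library totals alone, which shifted the median of all genes by -0.49 on the log2 scale.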

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

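The test of the difference between the 2 effects was planned, and the tests of explanations for it were chosen after the results were seen. The effect of infected RBC over uninfected RBC differed from that of LPS over medium for 166 genes by edgeR's test of the difference, 130 with the higher effect for infected RBC and 36 with the lower. Replicate number as a block raised the count to 653, and library totals alone, which shifted the median of all genes by 0.145 on the log2 scale, to 251. It was 1 without replicate 1 or 2 of uninfected RBC, replicate 1 or 2 of LPS, or replicate 2 of medium, 9 without replicate 1 of medium, 44 without replicate 1 of infected RBC and 382 without replicate 2 of infected RBC. HMOX1 was called without each of the 8 libraries, with a log2 difference between 6.57 and 7.18.

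The difference was called positive for few members of each list, such as 2 of 26 haem genes, 1 of 26 lysosome genes and 2 of 16 dendritic cell identity genes. A positive difference need not be a rise with infected RBC. CLEC10A, HLA-DOA, CD14 and LPCAT3 fell in both comparisons, and fell less with infected RBC. HMOX1 differed by 6.85 on the log2 scale (SE 0.37, adjusted p = 0.00206), opposite in sign in the 2 comparisons, and SLC48A1, the lysosomal haem transporter, by 2.89. CTSD, a lysosomal protease, differed by 4.88. Of the dendritic cell identity genes, CLEC10A differed by 4.07 and ITGAX by 1.65, and the class II gene HLA-DOA by 2.19. CD14, the co-receptor for LPS, differed by 2.66, CD5 by 3.76, the transcription factor SPIB by 3.67, the cytokine OSM by 1.77, LPCAT3 by 2.05 and EPB41 by 2.11. The steepest differences among genes outside the lists were 7.50 for MPZL2, whose size is uncertain because it had 0 reads with LPS, 5.12 for SDS, 5.10 for COL23A1 and 5.09 for CAMKK1.

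The difference was negative for genes whose log2 fold change was higher with LPS, among them CHAC1, which fell with infected RBC and rose with LPS. IL23A, a subunit of IL-23, differed by -4.50 and CXCL2, a chemokine for neutrophils, by -2.55. With RLE size factors the adjusted p of IL23A, OSM, SPIB and COL23A1 was 0.0504 to 0.0524, and these 4 were no longer called. The glycolytic enzyme PGAM1 differed by -1.60 and CHAC1, a stress gene, by -2.56. Outside the lists, DIRC3 differed by -5.72, RGL4 by -4.88, SLC35G1 by -3.89 and CACNB3 by -3.65.

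Of the 11 lists called for the difference, 5 favoured infected RBC and 6 LPS, and none was called with an estimated correlation. Favouring infected RBC was often a smaller fall. The median log2 fold changes with infected RBC and with LPS were -1.68 and -2.86 for identity, -0.66 and -1.44 for monocyte and -0.03 and -1.13 for class II genes. Lysosome (0.74 and -0.51) and LXR medians (0.92 and -0.58) differed in sign. All 6 lists in favour of LPS had medians above 0 in both comparisons. CD1c+ dendritic cell identity (10 of 16 members higher and 0 lower adjusted over the list alone, camera adjusted p = 2.05e-07, adjusted p = 0.102 with an estimated correlation) and MHC class II presentation (9 of 20 and 0, adjusted p = 1.61e-06, adjusted p = 0.209 with an estimated correlation) favoured infected RBC. Phagosome and lysosome genes did so as well (13 of 26 and 1, adjusted p = 1.7e-05, adjusted p = 0.263 with an estimated correlation), with LXR targets (5 of 15 and 0, adjusted p = 0.00215, adjusted p = 0.209 with an estimated correlation) and monocyte genes (5 of 15 and 0, adjusted p = 0.00215, adjusted p = 0.256 with an estimated correlation). The lists in favour of LPS held few called members. They were type I interferon-stimulated genes (adjusted p = 3.88e-05), interferon-gamma-inducible genes (adjusted p = 0.0302) and cytokines (adjusted p = 0.0219), each with an adjusted p = 0.659 with an estimated correlation. The others were stress genes (adjusted p = 4.69e-05, adjusted p = 0.459 with an estimated correlation), MHC class I presentation (adjusted p = 9.83e-05, adjusted p = 0.577 with an estimated correlation) and NF-kappaB targets (adjusted p = 0.0229, adjusted p = 0.667 with an estimated correlation). With replicate number as a block the test called 4 identity, 6 class II, 5 LXR, 4 monocyte, 5 haem and 4 lysosome genes higher and 1 lysosome, 4 stress, 1 type I interferon-stimulated and 1 class I gene lower. Cholesterol synthesis had an adjusted p = 0.0747, or 0.0305 with replicate number as a block.

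In the first pattern, genes that fell with LPS and rose with infected RBC, a one-sided test over the 2653 genes lower with LPS passed 6 for a rise with infected RBC (FSTL3, HBEGF, HMOX1, PELATON, RALGDS and UAP1L1), and edgeR's test passed 0 of 2771 genes the other way round. Library scaling is unlikely to have made the result for HMOX1, whose adjusted p was at most 0.0162 over TMM, RLE size factors and library totals, or the rise of the other 5, whose log2 fold changes were 1.42 (SE 0.22) to 2.94 (SE 0.41) with TMM, 1.45 (SE 0.21) to 2.97 (SE 0.41) with RLE size factors and 0.93 (SE 0.24) to 2.47 (SE 0.39) with library totals. None of those 5 passed the one-sided test with the other scalings, from adjusted p of 0.0357 to 0.0479 with TMM. Of the 5, 3 were called lower with LPS in each scaling. FSTL3 and RALGDS were not called lower with RLE size factors, where their log2 fold changes moved little from TMM (-1.28 to -1.23, SE 0.43, and -0.57 to -0.52, SE 0.19). With library totals both fell further and were called (-1.89, SE 0.41, and -1.20, SE 0.22). Scaling stays open for whether these 2 falls are called. Of 86 genes changed 2-fold both ways in replicate 1, 59.3% moved in these directions in replicate 2, against 11.1% of all genes. In the other order it was 71.4% of 49 genes against 12.6%. These shares cannot tell whether libraries of one replicate number made the first pattern. Genes chosen as lower with LPS may fall with LPS again, so all genes are too lax a comparison for their rise. For HMOX1 alone, the log2 difference of effects stayed between 6.57 and 7.18 whichever library was left out. Haem or haemozoin, the haem crystal made by the parasite, from the infected cells is a candidate explanation that stays open, because the haem, iron and oxidative response list had an adjusted p = 0.054 for the difference (0.65 with an estimated correlation) and no group received haem or haemozoin alone.

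The second pattern was the smaller size of the changes with infected RBC than with LPS, a ratio of 0.654 over all 13892 genes, from products of the 2 replicate numbers so that no choice of genes enters. Library scaling is an unlikely cause, with ratios of 0.654 for RLE size factors and 0.661 for library totals. A single infected library is unlikely too: over genes changed 2-fold with infected RBC in one replicate number, a choice that favours infected RBC, the ratio in the other was 0.686 in replicate 1 and 0.838 in replicate 2. Endotoxin carried with the infected cells, acting as a weaker LPS exposure in the same direction at every dose, could give the 2291 genes called in the same direction, and the design cannot separate it from a response to the parasite for them. Such an exposure would not raise HMOX1, whose log2 fold change with infected RBC was at least 2.71 and at most 3.23 in 17 settings. With LPS it lay between -4.28 and -3.39. The assumed direction at every dose could not be checked, since the design held a single LPS condition. HMOX1 also does not speak against endotoxin present beside another stimulus. The dose of parasites was not matched to the dose of LPS, so a difference in strength also stays open and was not tested.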

How the results depend on the processing

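The alternative of library totals without scaling factors was chosen after seeing the data, and the others before. Of the 526 called results chosen for naming over the 6 contrasts, 511 stayed called in the same direction with RLE size factors, 518 without a filter, 514 with DESeq2, 488 with limma-voom, 526 with the block, 413 of 496 with only the groups compared, 523 of 523 with haemoglobin genes removed and 489 with library totals. Leaving out 1 library kept 383 to 455, and 0 reversed in any setting. Data were simulated with n = 2, the depths at hand and 200 changed genes among 13294. There the test recovered 10.1% of 2-fold and 72.5% of 4-fold changes in the comparison of LPS with medium, so most 2-fold changes were missed. In the real comparison 5424 genes were called, of which 4421 changed at least 2-fold. With so many more calls the cut-off on the unadjusted p is looser, so the simulated rates do not carry over to it. Small changes may still have been missed.

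With replicate number as a block, which uses the pairing by donor, HBB with uninfected RBC was called and 2 lists crossed the threshold (cell death regulators with LPS and cholesterol synthesis in the difference of effects). NCAM1 with infected against uninfected RBC, IFNB1 with infected RBC against LPS, and NKG7 and MMP9 in the difference of effects were called too, and no named call was lost. Most numbers of list members that it moved by over 1.5 times stand beside the lists described, and those of lists not described in a contrast are left out. The counts of genes were 1 for uninfected RBC against medium (0 without it), 4302 for infected against uninfected RBC (2732), 4122 for infected RBC against medium (2521), 2429 for infected RBC against LPS (1247), 653 for the difference of effects (166) and 3479 for the calls shared by infected RBC and LPS (2291). With only the groups compared they were 1677, 1433 and 484 for infected RBC against uninfected RBC, medium and LPS, where fewer libraries inform the spread. Library totals gave 2, 4439, 4247, 251 and 3799 for uninfected RBC against medium, infected against uninfected RBC, infected RBC against medium, the difference of effects and the shared calls. No filter gave 3, 2483 and 1158, and DESeq2 2, 1943 and 753, for uninfected RBC against medium, infected RBC against LPS and the difference, for which limma-voom gave 100. The genes called for uninfected RBC against medium in these settings were HBB, HBA2 and HBA1 without a filter, HBB and HBA2 with DESeq2 and with library totals, and HBB with the block. Leaving out 1 library gave ranges of 0 to 1 for uninfected RBC against medium, 420 to 2433 for infected against uninfected RBC, 3044 to 5797 for LPS, 288 to 2257 for infected RBC against medium, 233 to 1229 for infected RBC against LPS, 1 to 382 for the difference and 395 to 2048 for the shared calls. Apart from the smaller number of libraries, the cause was not tested.

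Of the list tests, camera with a correlation estimated from the data called 0 lists in all 6 contrasts, where the preset correlation called 2, 17, 17, 16, 12 and 11. For type I interferon-stimulated genes with infected against uninfected RBC the estimate was 0.71, above the preset 0.01. For CD1c+ dendritic cell identity genes with infected RBC against LPS it was -0.047, below the preset. The camera adjusted p of that identity list still went from 2.17e-07 to 0.103. A higher correlation therefore does not account for every lost call. Removing haemoglobin genes left 1 of 2 for uninfected RBC against medium, since the erythroid list lost its haemoglobin genes. Without 1 library the lists called ranged from 2 to 12 for uninfected RBC against medium, 14 to 19 for infected against uninfected RBC, 12 to 18 for LPS, 14 to 17 for infected RBC against medium, 9 to 14 for infected RBC against LPS and 9 to 13 for the difference.

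Among the named genes that were not called, those that changed sign numbered 3. IL1B with uninfected RBC against medium was -0.01 in log2 fold change, 0.01 without a filter and 0.09 with limma-voom, and ranged from -0.47 to 0.68 without 1 library (positive without replicate 2 of uninfected RBC or replicate 1 of medium). CXCL8 there was 0.01 with limma-voom and ranged from -0.51 to 0.58, positive without the same libraries. IFNB1 with infected against uninfected RBC (0.33) was -0.13 with library totals and -0.10 without replicate 2 of infected RBC. The cause was not tested.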

Other observations

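Gene families that the fixed lists hold only in part or not at all were counted after the data were seen, with no test of enrichment. Of 10 measured leukocyte immunoglobulin-like receptors, which mostly set the threshold for myeloid cell activation, 5 rose and 0 fell by edgeR's test with infected over uninfected RBC, and 6 rose and 0 fell with LPS over medium. Of 37 proteasome subunits 10 rose with infected RBC and 24 with LPS, with 0 lower in either, though the family's median log2 fold change with infected RBC was 0.47 with TMM and turned to -0.00 with library totals. Of 8 tubulins, the building blocks of microtubules, 4 rose with infected RBC and 6 with LPS, and 0 fell.

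The next 3 families are set beside all 13892 genes, of which 19.9% rose and 19.1% fell with LPS, and 11.6% rose and 8.1% fell with infected RBC. Of 76 cytosolic ribosomal proteins 13 (17.1%) fell with LPS and 2 with infected RBC, and 0 rose in either. Of 47 NADH dehydrogenase subunits and assembly factors, of respiratory complex I, 14 (29.8%) fell and 3 rose with LPS, and 1 fell and 1 rose with infected RBC. Of 423 zinc-finger genes with ZNF symbols, mostly transcriptional repressors, 81 (19.1%) fell and 19 (4.5%) rose with LPS, and 30 fell and 8 rose with infected RBC. With TMM their median log2 fold changes with LPS were -0.25 for ribosomal proteins, -0.29 for complex I and -0.32 for zinc-finger genes, against -0.06 for all genes, and with library totals -0.88, -0.92 and -0.94 against -0.68.

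The haemoglobin reads with uninfected RBC were weighed after they were seen. HBA1, HBA2 and HBB together had 4021 and 1983 reads in replicates 1 and 2 of uninfected RBC, and the ratio of HBA2 to HBB was 0.266 and 0.414. RNA carried over from the added uninfected red blood cells stays open as a possible source. The 4 medium and LPS libraries, which received no red cells, held 1 such read together, but the infected RBC libraries, which did receive red cells, also held 1. The count of 1 in the medium and LPS libraries speaks against red blood cells left in the dendritic cell preparation, which would have reached all groups. Transcription of haemoglobin genes in the dendritic cells on contact with red blood cells stays open, because the infected RBC libraries held 1 read but the infected cells are not the same stimulus.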
